A study of Homo sapiens with 26 samples.

How the data were processed

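Total RNA from established human colorectal cancer cell lines was measured on 26 Agilent 1-colour (Cy3) arrays of design 026652. The cells were DLD1, a DLD1 derivative carrying an added chromosome 7 (DLD1+chr7 in the titles, written DLD1+7 here), and SW480, each given trichostatin A (TSA, a hydroxamic acid that inhibits histone deacetylases) at 160 nM for 24 h, or DMSO vehicle. Per the labels, DLD1 cells grew in RPMI and SW480 cells in DMEM, and DLD1+7 cells were also kept in G418, so medium and selection differ between lines.

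The authors scanned the arrays with Agilent Feature Extraction 10.7.3.1, and the deposited spot values are an intensity that, per the file headers, is background subtracted and detrended within each array but not scaled between arrays. The deposited files also carry other columns, which are flags of 0 or 1 for spots well above background, saturated or irregular. The series table deposited by the authors holds values that behave as log2 signal for 27894 of the 34127 probes. How the authors scaled that table is not stated. Against log2 of the scanner signal its slopes ran from 0.975 to 1.28 between arrays with a rank correlation of at least 0.9996, so fold changes from it are not on a plain log2 scale and it served only as an alternative. No column of mean spot signal is in the files, so the background correction tried as an alternative used the spot medians.

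Each array had 43118 spots outside the 1377 controls. Log2 signals were averaged over the spots of a probe, and the 75th percentile of each array was subtracted. Of the probes, 25771 (75.5%) carry exactly 1 gene symbol, none carries several, and 8356 carry no gene symbol and were left out of the gene tests. The brightest probe stood for each of 19740 genes. A gene was tested when its probe was well above background on every array of at least 1 group of the fit. Genes silent under vehicle thus entered only through a group where they were detected. This favours rises in lists of genes that the cells barely express. The arrays were annotated on hg19 and the chromosome arms were taken from a GRCh38.p14 gene table, so only chromosome, arm and gene order are given here and no coordinates. Depth cannot be given as counts for arrays, and their number limits the precision.

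Differences were fitted with limma 3.58.1 in R 4.3.3, with group means and moderated variances, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. DLD1 and DLD1+7 shared a fit of 17 arrays, SW480 had its own, and the difference in response between SW480 and DLD1 used all 26 arrays. Standard errors of gene changes are those of limma. Those of chromosome 7 scores come from the spread between arrays. Those of differences between parts of chromosome 7 come from 2000 bootstrap draws of genes, which treat genes as independent although they are not. A fold against a group whose probe was not well above background on its arrays is given as a lower bound: signals under an array's lowest well-above-background signal were raised to that level before the group means were compared.

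In all, 33 gene lists with 836 members on the array were tested with cameraPR of limma, which ranks a list against all other genes, with a preset correlation of 0.01 between genes. It stood in for camera so that fits with blocks could be tested alike, and camera was run again with the correlation estimated from the arrays. Adjusted p-values for lists cover the 33 lists of a comparison. Chromosome shifts are the mean log2 fold change of a chromosome's genes minus that of all other genes, tested in the same way. For each array a chromosome 7 score was also made from the genes tested in its fit. It is the mean log2 signal of chromosome 7 genes minus that of all others. The scores were compared by two-sided exact permutation of arrays, with 95% confidence intervals from a normal approximation. For groups of so few arrays these intervals are too narrow. Overlaps and shares were tested with the two-sided Fisher's exact test, which treats genes as independent although they are not. Files were read and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

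The comparisons, lists, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 8 largest rises and the 8 largest falls of each TSA response and of the chromosome 7 gain under vehicle, among called genes whose arrays do not overlap between the groups. For the gain under TSA and the differences in response it named 5 and 5. It also named the 8 largest rises on chromosome 7, the 8 largest falls with TSA among raised chromosome 7 genes, up to 3 members of each list, and, among genes fixed by name, CDKN1A, MYC, AXIN2, EGFR, MET, BRAF, CDK6 and EZH2. Y-linked genes and XIST were left out.

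The alternatives were quantile scaling, centring on each array's median, normexp background correction with an offset of 50, no filter and a stricter filter on dim probes, the mean of a gene's probes, the authors' table, a trend with robust variances, fits of the compared groups alone or of all arrays, the replicate number or the slide as a block, and leaving out each array in turn. Normexp without spots lying more than 50 below their local background, a fit without the dimmest slide, and list tests with each array left out in turn, were added after seeing the data. Recovery of known changes was tested on simulated data built on the fitted means and variances.

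The labels do not state whether replicates are separate cultures, so the p-values measure only the spread between these samples. The 26 arrays lay on 12 slides and were scanned on 2 days. All SW480 arrays were scanned on a different day from all DLD1 and DLD1+7 arrays, so scan day and line cannot be told apart. For 1 array, DLD1+7 TSA replicate 5, the title gives DLD1+chr7 and a cell line label gives SW480. Its mean correlation across genes was 0.977 with the other DLD1+7 TSA arrays and 0.808 with the SW480 TSA arrays, and it was kept in the DLD1+7 group. DLD1 vehicle replicate 1 correlated most with DLD1+7 vehicle replicate 2, on the same slide (0.959). With its own group its mean correlation was 0.949, and it was kept there by its title.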

Results

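Gene expression was measured in 6 groups of cells: 3 DLD1 vehicle arrays, 5 DLD1 TSA, 4 DLD1+7 vehicle, 5 DLD1+7 TSA, 3 SW480 vehicle and 6 SW480 TSA. DLD1 and SW480 are colorectal adenocarcinoma lines, and the added chromosome 7 of DLD1+7 models a gain that is common in colorectal tumours. The 75th percentile of the scanner signal, in intensity units, lay between 434 and 1729 in DLD1 vehicle, 640 and 1719 in DLD1 TSA, 1195 and 1794 in DLD1+7 vehicle, 919 and 1504 in DLD1+7 TSA, 2072 and 2612 in SW480 vehicle, and 1204 and 2481 in SW480 TSA. The lowest, 434, was that of DLD1 vehicle replicate 1. Between 64.8% and 80.3% of probes were well above background on an array.

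The first question was what the deacetylase inhibitor changed in DLD1. After TSA, the lists of DNA replication, mitosis, ribosome biogenesis and cholesterol synthesis genes stood lower, and those of metallothioneins, interferon-stimulated genes and NRF2 targets higher. These calls used a preset correlation between genes, and none was kept with an estimated one (lowest adjusted p = 0.0583 with an estimated correlation). Genes that DLD1 barely expressed appeared, among them the interleukin receptor subunit IL3RA, at least 149-fold higher (adjusted p = 4.93e-11), and the secretoglobin SCGB2A1, at least 132-fold higher. The galectin LGALS1 rose by 6.90 on the log2 scale (SE 0.38), the water channel AQP3 by 6.77 (SE 0.34) and haemoglobin HBB by 6.42 (SE 0.39), each with n = 5 against 3. The largest falls included the Notch glycosyltransferase LFNG (log2 change -3.85, SE 0.52), the transcription factor MYB (-3.48, SE 0.57), the recombination helicase RAD54L (-3.42, SE 0.41) and the replication origin factor CDC45 (-3.23, SE 0.42). For all genes of largest change named here and for the other lines below, the arrays of the compared groups did not overlap. HBB in DLD1, TFPI2 and IL3RA in DLD1+7, FTCD, NEFH, EDN3 and KCNJ5 in SW480, and DENND2D, SATB1, KRT20 and MDFIC between DLD1+7 and DLD1 lacked a signal well above background on some arrays of the lower group, so the sizes given for them are less certain than the SE shows.

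In DLD1, limma called 5981 of 15564 genes, 3230 higher and 2751 lower with TSA. Of the called genes 54.0% were higher, against 39.7% with each array centred on its median, a scaling that put the median change of all genes at -0.21, so small changes in either direction depend on the scaling. Of 40 DNA replication genes 34 fell and none rose (37 fell when adjusted over the list alone), among them TYMS, the thymidylate synthase (-3.19, SE 0.53; list adjusted p = 2.83e-13, adjusted p = 0.149 with an estimated correlation). Of 31 mitosis genes 26 fell (27 adjusted over the list alone), with AURKB at -2.90 (SE 0.60; list adjusted p = 5.18e-10, adjusted p = 0.226 with an estimated correlation). Homologous recombination and Fanconi genes fell in 21 of 27 cases and rose in 1 (the same 21 and 1 adjusted over the list alone; adjusted p = 1.47e-07, adjusted p = 0.160 with an estimated correlation). MYC targets and ribosome biogenesis genes fell in 26 of 32 cases (28 adjusted over the list alone), with SRM at -1.83 (list adjusted p = 2.48e-08, adjusted p = 0.149 with an estimated correlation), although MYC itself was higher (1.22, SE 0.29).

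Genes known to answer deacetylase inhibitors rose in 13 of 19 cases and fell in 1 (15 and 1 adjusted over the list alone). They included the dehydrogenase DHRS2 (4.63, SE 0.46) and clusterin, CLU (3.93, SE 0.27), and 9 of the members listed are shared with other lists (list adjusted p = 1.01e-06, adjusted p = 0.149 with an estimated correlation). The CDK inhibitor gene CDKN1A rose by 1.70 (SE 0.37, adjusted p = 0.00161), a call lost under normexp (0.31) and under normexp without far spots (0.65). Metallothioneins, which bind zinc and copper, rose in 10 of 11 cases (11 adjusted over the list alone), with MT1X at 2.12 (SE 0.26; list adjusted p = 0.000249, adjusted p = 0.247 with an estimated correlation). Immediate early and AP-1 genes rose in 14 of 24 cases and fell in 1 (15 and 1 adjusted over the list alone), with the phosphatases DUSP5 (4.77, SE 0.33) and DUSP6 (3.56, SE 0.20; list adjusted p = 2.29e-05, adjusted p = 0.226 with an estimated correlation). Of 33 interferon-stimulated genes 16 rose and 3 fell (18 and 4 adjusted over the list alone), with OASL at 4.55 (SE 0.37; list adjusted p = 0.00332, adjusted p = 0.149 with an estimated correlation). NRF2 targets rose in 11 of 22 cases and fell in 1 (the same adjusted over the list alone), with AKR1C3 at 4.18 (SE 0.17; list adjusted p = 5.19e-05, adjusted p = 0.102 with an estimated correlation).

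Cholesterol and fatty acid synthesis genes fell in 20 of 30 cases in DLD1 and rose in 1 (the same adjusted over the list alone), with MVK at -1.58 (SE 0.22) and DHCR7 at -1.54 (SE 0.14; list adjusted p = 1.40e-05, adjusted p = 0.0816 with an estimated correlation). Heat shock proteins and chaperones fell in 14 of 21 cases (14 adjusted over the list alone), with HSPH1 at -2.12 (SE 0.28; list adjusted p = 4.54e-05, adjusted p = 0.0583 with an estimated correlation). Proteasome genes fell in 13 of 31 cases (13 adjusted over the list alone), with PSMB5 at -1.24 (SE 0.19; list adjusted p = 0.000223, adjusted p = 0.149 with an estimated correlation). Histone acetyltransferase and bromodomain genes fell in 8 of 15 cases (8 adjusted over the list alone), with KAT2A at -1.50 (list adjusted p = 0.0369, adjusted p = 0.247 with an estimated correlation, 0.0933 with the slide as a block). Polycomb and DNA methylation genes fell in 9 of 18 cases and rose in 2 (9 and 3 adjusted over the list alone), with UHRF1 at -2.31 (list adjusted p = 0.0426, adjusted p = 0.149 with an estimated correlation, 0.0816 with the slide as a block and 0.0664 with the replicate number as a block). Mesenchymal genes rose in 7 of 20 cases and fell in 2 (the same adjusted over the list alone), with VIM at 5.08 (SE 0.30; list adjusted p = 0.0278, adjusted p = 0.247 with an estimated correlation). Their median of 0.17 became -0.03 under median centring. The call of each of these last 3 lists was lost in at least 1 fit with an array left out. Glycolysis and hypoxia genes (adjusted p = 0.0165, adjusted p = 0.457 with an estimated correlation) and fibroblast and endothelial markers (adjusted p = 0.00691, adjusted p = 0.149 with an estimated correlation) also stood higher. No list call in any comparison was kept with an estimated correlation, where the lowest adjusted p was 0.0583, and in DLD1 10 lists then had an unadjusted p under 0.05.

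**Figure D1:**
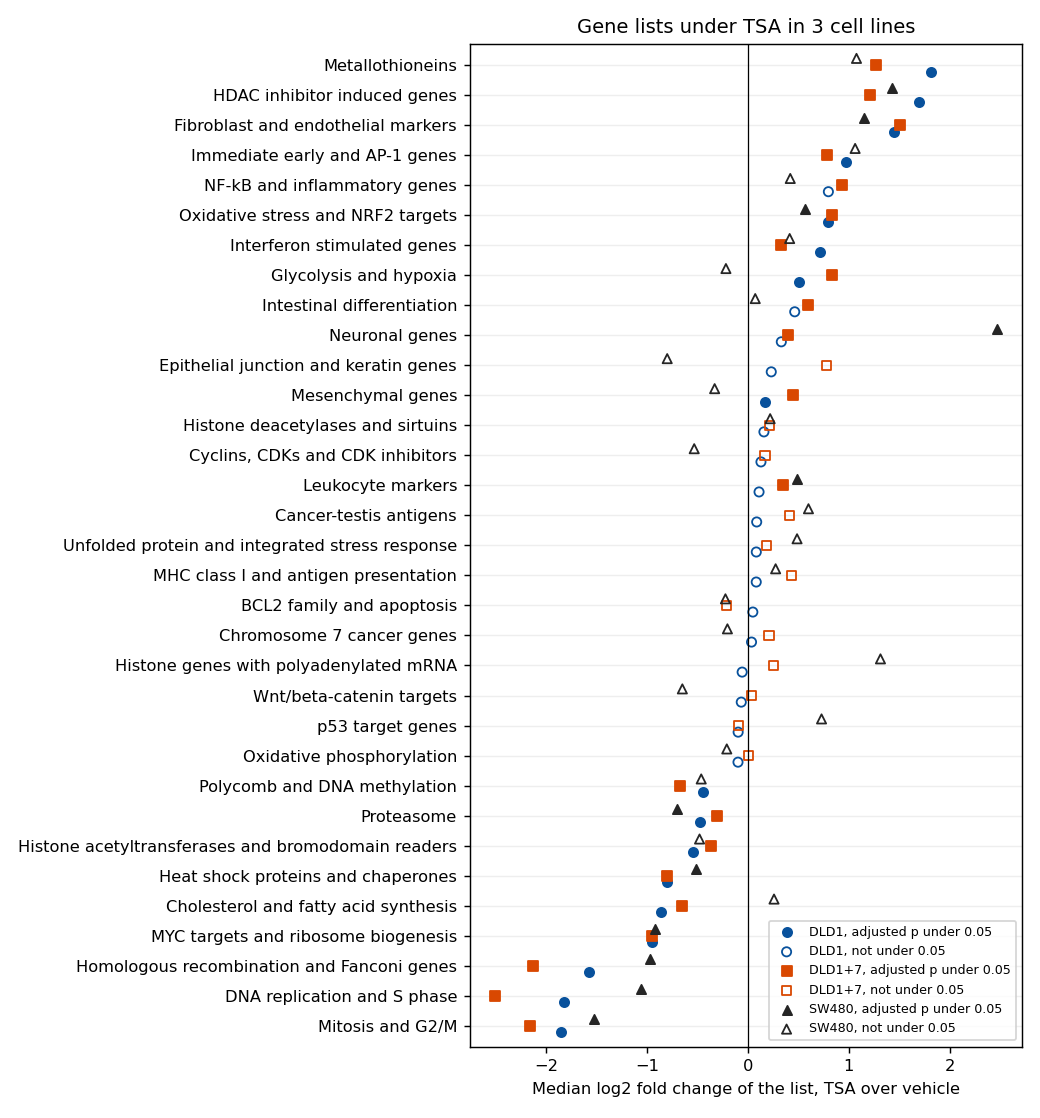
Median log2 fold change with TSA of the genes of each list in DLD1, DLD1+7 and SW480, with filled points where the list's adjusted p was under 0.05. DNA replication genes had medians of -1.82, -2.51 and -1.06, and the neuronal genes of SW480 a median of 2.47.

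The same exposure was compared with vehicle in DLD1+7, to ask whether the cells with the added chromosome answered the drug. The lists of DNA replication, mitosis and recombination genes stood lower, and those of NRF2 targets, interferon-stimulated and inflammatory genes higher. None of these calls was kept with an estimated correlation (lowest adjusted p = 0.0985 with an estimated correlation). SCGB2A1 was at least 159-fold higher and the prostaglandin synthase PTGS1 at least 82.8-fold higher (n = 5 against 4). The protease inhibitor gene TFPI2, on 7q, rose by 7.19 (SE 0.66) and IL3RA by 7.04 (SE 0.27). MYB (-3.87, SE 0.52), TYMS (-3.86, SE 0.48), the stress gene NUPR1 (-3.66, SE 0.53) and ASB4, also on 7q (-3.81, SE 0.41), fell most.

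In DLD1+7, limma called 6480 of 15564 genes, 3517 higher and 2963 lower. The share higher was 54.3%, against 39.0% under median centring, where the median of all genes moved from 0.06 to -0.17. DNA replication genes fell in 39 of 40 cases (39 adjusted over the list alone), with MCM5 at -3.29 (SE 0.39; list adjusted p = 4.40e-22, adjusted p = 0.103 with an estimated correlation). Mitosis genes fell in 28 of 31 cases (31 adjusted over the list alone), with CCNA2 at -3.23 (SE 0.60; list adjusted p = 8.95e-13, adjusted p = 0.184 with an estimated correlation). Homologous recombination and Fanconi genes fell in 24 of 27 cases and rose in 1 (25 and 1 adjusted over the list alone), with EXO1 at -2.90 (list adjusted p = 1.58e-12, adjusted p = 0.103 with an estimated correlation). Of 18 Polycomb and DNA methylation genes 10 fell and 2 rose (the same adjusted over the list alone), with UHRF1 at -3.09 (SE 0.29; list adjusted p = 0.00142, adjusted p = 0.0985 with an estimated correlation). NRF2 targets rose in 12 of 22 cases (14 rose and 1 fell adjusted over the list alone), with AKR1C3 at 3.39 (SE 0.15; list adjusted p = 5.84e-05, adjusted p = 0.0985 with an estimated correlation). Glycolysis and hypoxia genes rose in 16 of 27 cases and fell in 3 (17 and 3 adjusted over the list alone), with ALDOC at 3.47 (SE 0.28; list adjusted p = 0.00100, adjusted p = 0.268 with an estimated correlation). NF-kB and inflammatory genes rose in 13 of 24 cases and fell in 1 (the same adjusted over the list alone), with BIRC3 at 4.76 (SE 0.42; list adjusted p = 0.00773, adjusted p = 0.103 with an estimated correlation). Intestinal differentiation genes rose in 11 of 25 cases (11 adjusted over the list alone), with DPP4 at 3.16 (SE 0.24; list adjusted p = 0.0108, adjusted p = 0.181 with an estimated correlation). Markers of other cell types rose with them: fibroblast and endothelial markers in 6 of 9 cases (6 adjusted over the list alone; adjusted p = 0.0108, adjusted p = 0.150 with an estimated correlation) and leukocyte markers in 5 of 15 (5 adjusted over the list alone; adjusted p = 0.0223, adjusted p = 0.347 with an estimated correlation). The array held 20 fibroblast and endothelial markers and 20 leukocyte markers. Members not well above background throughout any group were not tested, so the filter favours rises among markers silent under vehicle. In all 21 lists were called, and with an estimated correlation 9 had an unadjusted p under 0.05.

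In SW480 the lists of DNA replication, mitosis and proteasome genes stood lower with TSA, and those of neuronal genes and of fibroblast and endothelial and leukocyte markers higher. None of these calls was kept with an estimated correlation (lowest adjusted p = 0.199 with an estimated correlation). The immunity-related GTPase gene IRGM was at least 884-fold higher with TSA and the guanylate-binding protein GBP5 at least 130-fold higher, and RFPL4A (8.78, SE 0.33) and the folate enzyme gene FTCD (8.70, SE 0.43) rose with n = 6 against 3. Endothelin 3, EDN3 (-5.47, SE 0.71), FGF3 (-5.23, SE 0.78), the potassium channel gene KCNJ5 (-4.97, SE 0.44) and CACNG6 (-4.58, SE 0.23) fell most. CDKN1A stood at 0.73 (SE 0.20, adjusted p = 0.00968), a call lost under quantile scaling (0.40) and under median centring (0.37). MYC stood at -0.03 (adjusted p = 0.964) and at 0.60 (adjusted p = 0.0324) with the replicate number as a block, and its sign also turned without any of 5 single arrays.

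In SW480, limma called 8576 of 14696 genes, 4427 higher and 4149 lower. The share higher was 51.6%, against 33.2% under median centring, which put the median of all genes at -0.36. Neuronal genes rose in 22 of 27 cases and fell in 1 (22 and 2 adjusted over the list alone): SYT11 was at least 40.4-fold higher, STMN2 at least 24.6-fold, and the neurofilament gene NEFH rose by 6.51 (SE 0.93; list adjusted p = 1.45e-08, adjusted p = 0.199 with an estimated correlation). Markers of other cell types rose too: fibroblast and endothelial markers in 4 of 6 cases (4 adjusted over the list alone; adjusted p = 0.00126, adjusted p = 0.199 with an estimated correlation) and leukocyte markers in 6 of 13 (6 adjusted over the list alone; adjusted p = 0.0329, adjusted p = 0.199 with an estimated correlation), the call of the latter being lost without SW480 vehicle replicate 2 or 3. Mitosis genes fell in 29 of 31 cases (29 adjusted over the list alone), with CCNA2 at -2.71 (SE 0.24; list adjusted p = 1.27e-09, adjusted p = 0.250 with an estimated correlation). DNA replication genes fell in 33 of 40 cases and rose in 1 (the same adjusted over the list alone), with TYMS at -3.68 (SE 0.27; list adjusted p = 2.46e-08, adjusted p = 0.199 with an estimated correlation). MYC targets and ribosome biogenesis genes fell in 25 of 32 cases and rose in 1 (the same adjusted over the list alone), with UTP20 at -2.47 (SE 0.17; list adjusted p = 4.65e-06, adjusted p = 0.199 with an estimated correlation). Proteasome genes fell in 21 of 31 cases and rose in 1 (22 and 1 adjusted over the list alone), with PSMB5 at -1.89 (SE 0.17; list adjusted p = 4.32e-05, adjusted p = 0.250 with an estimated correlation). Genes known to answer deacetylase inhibitors rose in 16 of 19 cases and fell in 1 (the same adjusted over the list alone), with DHRS2 at 5.12 (SE 0.24) and TXNIP at 4.50 (SE 0.26; list adjusted p = 3.44e-05, adjusted p = 0.199 with an estimated correlation). Interferon-stimulated genes (adjusted p = 0.0733), metallothioneins (0.0806) and the unfolded protein response (0.101) were not called, and each was called with the replicate number as a block (0.0107, 0.0356 and 0.0299) but not with the slide as a block (0.0738, 0.0951 and 0.108). The array held 36 neuronal genes, 20 fibroblast and endothelial markers and 20 leukocyte markers, and only those tested are counted above. Members not well above background throughout either SW480 group were left out, so the filter favours rises among genes silent under vehicle. In all 11 lists were called, and with an estimated correlation 6 had an unadjusted p under 0.05. On the slides that held both TSA and vehicle arrays (3 for DLD1, 4 for DLD1+7 and 2 for SW480), the median of DNA replication genes lay between -2.28 and -1.67, between -2.67 and -1.85, and between -1.01 and -0.94. Every list called in these responses kept the sign of its median on each slide, except the Polycomb and DNA methylation genes of DLD1 on 1 of 3.

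**Figure D2:**
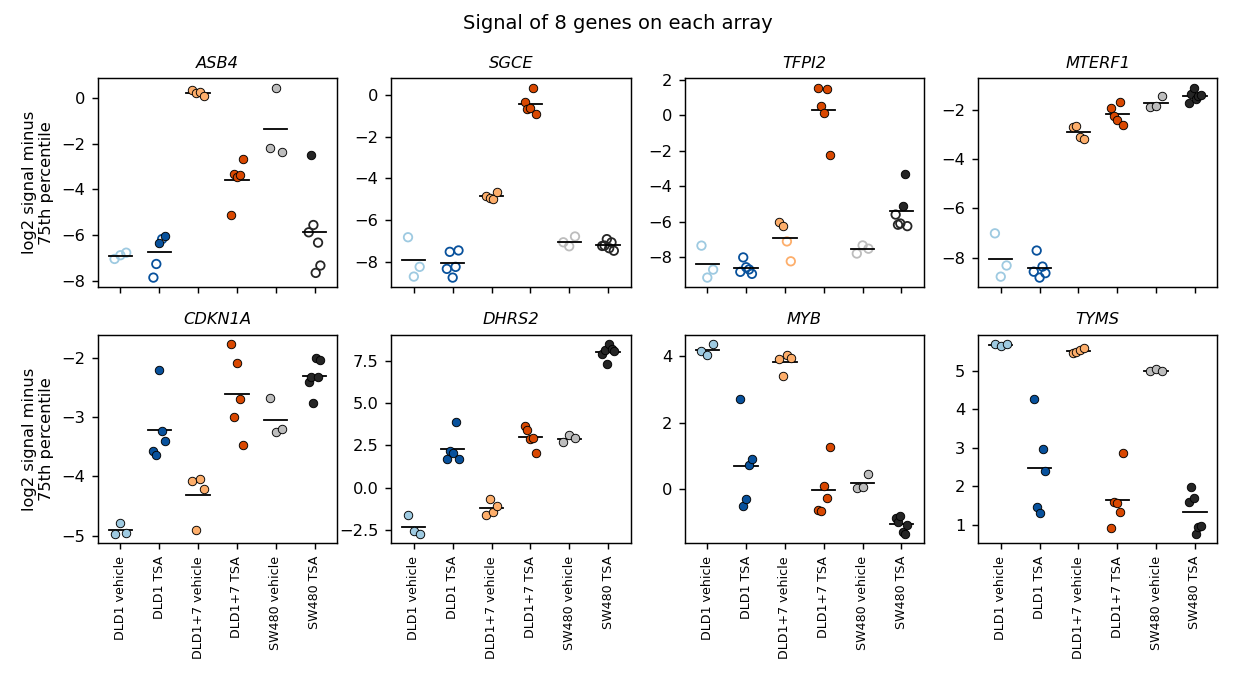
Log2 signal relative to the array's 75th percentile of 8 genes on every array, by group, with bars at group means, filled points for probes well above background and open points for the others. DHRS2 was higher with TSA by 4.63 in DLD1, 4.18 in DLD1+7 and 5.12 in SW480, and MTERF1, SGCE, TFPI2 and ASB4 are genes of 7q.

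Across the genes tested in both fits, the TSA responses of DLD1 and DLD1+7 correlated with r = 0.885 (Spearman 0.855), and 2678 genes rose and 2255 fell in both lines, against 730 and 524 for independent calls. Only 6 genes were called in opposite directions. DLD1 and SW480 correlated with r = 0.593 (Spearman 0.579), sharing 1979 rises and 1834 falls, with 374 genes opposite. DLD1+7 and SW480 correlated with r = 0.604. In all 3 lines 1735 of 14063 genes rose and 1609 fell. These correlations are across genes, which are not independent replicates.

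Cells with and without the added chromosome were compared under vehicle, to ask how the gain alters expression from chromosome 7 and elsewhere. DLD1+7 cells expressed genes of 7q at a higher level than DLD1 and held several genes that DLD1 barely expressed. ASB4, an ankyrin repeat gene of 7q, was at least 88.1-fold higher in DLD1+7 (adjusted p = 4.22e-08), CNPY1 at least 22.4-fold, MTERF1 at least 10.2-fold and GNG11 at least 7.36-fold. MDFIC (5.12, SE 0.44) and the hedgehog receptor SMO (4.34, SE 0.28), both on chromosome 7, were higher with n = 4 against 3. Off chromosome 7, KRT20 was higher (5.03, SE 0.51), and DENND2D (-8.40, SE 0.72) and the chromatin organiser SATB1 (-6.45, SE 0.59) were lower. The helicase HLTF was at least 59.0-fold lower, the stem cell marker PROM1 at least 15.7-fold and the homeobox gene DLX6, itself on chromosome 7, at least 24.0-fold.

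Under vehicle, limma called 1525 of 15564 genes, 845 higher and 680 lower in DLD1+7. The share higher was 55.4%, against 63.2% with quantile scaling, 63.7% with the authors' values, 47.2% with the slide as a block and 43.2% under normexp without far spots. On chromosome 7, 93 of 750 genes were higher (12.4%, against 5.08% elsewhere; Fisher's exact p = 4.03e-14) and 19 lower (2.53% against 4.46%). The mean shift of chromosome 7 genes was 0.26 on the log2 scale (a fold of 1.20; p = 5.97e-05, or 0.00383 with an estimated correlation), with a median of 0.19. Other chromosomes shifted by between -0.11 and 0.14. The 503 genes of 7q shifted by 0.35 (p = 7.77e-07, or 0.00142 with an estimated correlation) and the 247 of 7p by 0.087 (p = 0.147, or 0.215). Compared between arrays, the 7p score was also higher in DLD1+7, by 0.092 (95% interval 0.039 to 0.14, exact permutation p = 0.0286). The difference of the 2 arms, taken per array, was 0.26 (SE 0.02, n = 4 against 3, exact permutation p = 0.0286, the smallest that 35 splits can give). Among 27 chromosome 7 cancer genes 4 were higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.0513, 0.0259 with the slide as a block, 0.0938 with the replicate number as a block and adjusted p = 0.278 with an estimated correlation). EGFR (0.43), MET (0.01) and CDK6 (0.22) were not called, and neither was BRAF (0.46), which was called without DLD1 vehicle replicate 1 (0.75).

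**Figure D3:**
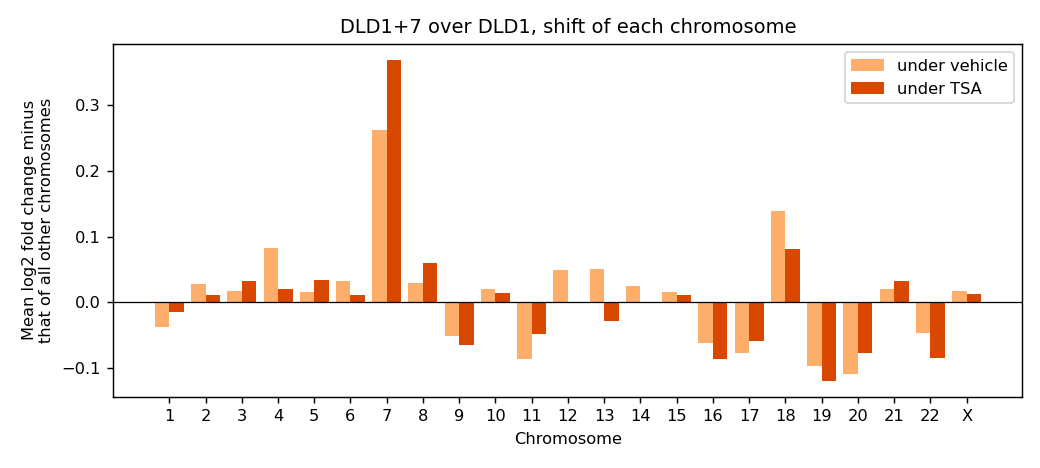
Mean log2 fold change of the genes of each chromosome minus that of all other genes, DLD1+7 over DLD1, under vehicle and under TSA. Chromosome 7 stood at 0.26 under vehicle and 0.37 under TSA, while the other chromosomes lay between -0.11 and 0.14 under vehicle.

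Among the lists, immediate early and AP-1 genes were higher in 6 of 24 cases (10 adjusted over the list alone), with KLF2 at 3.62 (SE 0.39; list adjusted p = 3.03e-06, adjusted p = 0.304 with an estimated correlation). Metallothioneins were higher in 6 of 11 cases (8 adjusted over the list alone), with MT1X at 1.66 (SE 0.27; list adjusted p = 0.000216, adjusted p = 0.422 with an estimated correlation). Cholesterol and fatty acid synthesis genes were lower in 7 of 30 cases (10 adjusted over the list alone), with LSS at -1.09 (SE 0.12; list adjusted p = 1.74e-05, adjusted p = 0.204 with an estimated correlation). Proteasome genes were lower in 6 of 31 cases (10 adjusted over the list alone), with PSMD3 at -0.82 (list adjusted p = 0.000543, adjusted p = 0.278 with an estimated correlation). Intestinal differentiation genes were lower in 4 of 25 cases and higher in 1 (5 and 1 adjusted over the list alone), with the microvillus gene VIL1 at -4.04 (SE 0.26) against the rise of KRT20 (list adjusted p = 0.00842, adjusted p = 0.343 with an estimated correlation), a call lost without DLD1 vehicle replicate 3. In all 7 lists were called, and with an estimated correlation 4 had an unadjusted p under 0.05. DLD1+7 differs from DLD1 also by its derivation and G418, so these differences are not of the chromosome alone.

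Under TSA the same lines were compared, to ask whether the gain still showed. TFPI2 was at least 119-fold higher in DLD1+7, SGCE at least 72.6-fold, GNG11 at least 47.9-fold and MTERF1 at least 21.8-fold (n = 5 against 5), all genes of 7q. HLTF was at least 114-fold lower and DENND2D stood at -7.28 (SE 0.60). Of 15564 genes, limma called 1595, 841 higher and 754 lower, and 464 genes were higher and 322 lower under both vehicle and TSA (45.7 and 32.9 for independent calls). On chromosome 7, 128 genes were higher (17.1% against 4.81% elsewhere; Fisher's exact p = 1.21e-32). The shift of chromosome 7 was 0.37 (a fold of 1.29; p = 6.36e-10, or 0.000163 with an estimated correlation), with 0.50 on 7q and 0.11 on 7p (p = 0.0793 across genes with the preset correlation, exact permutation p = 0.0159 between arrays). DNA replication genes were lower in 6 of 40 cases (8 adjusted over the list alone), with LIG1 at -1.28 (list adjusted p = 1.33e-05, adjusted p = 0.502 with an estimated correlation). Immediate early and AP-1 genes were higher in 7 of 24 cases and lower in 1 (8 and 2 adjusted over the list alone), with KLF2 at 3.99 (list adjusted p = 0.00100, adjusted p = 0.502 with an estimated correlation). In all 6 lists were called, of which 3 kept their call without DLD1 TSA replicate 1 and 5 without DLD1+7 TSA replicate 1. With an estimated correlation 2 lists had an unadjusted p under 0.05. Within slides their medians kept their sign on 5 of 5 slides for cholesterol, on 4 of 5 for DNA replication and on 3 of 5 for the immediate early genes.

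**Figure D4:**
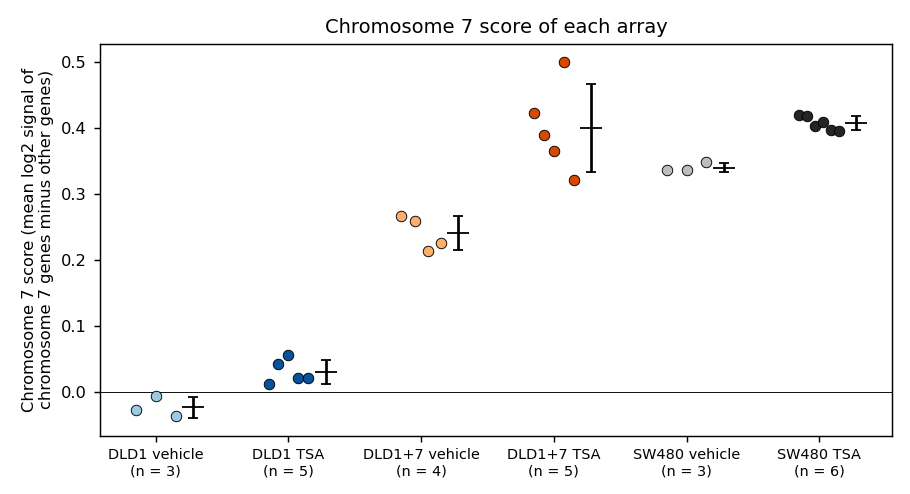
Chromosome 7 score of each array, the mean log2 signal of chromosome 7 genes minus that of other genes, with the group mean and SD. DLD1 vehicle arrays had a mean of -0.02 and DLD1+7 vehicle arrays 0.24. Scores of SW480 rest on 716 chromosome 7 genes and those of the other lines on 750. Their levels can therefore not be compared between SW480 and the other lines.

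Whether TSA takes away the raised expression of chromosome 7 was then measured. Chromosome 7 scores of SW480 rest on the genes tested in its own fit, so their level cannot be set against that of the other lines. The chromosome 7 score was -0.02 ± 0.02 in DLD1 vehicle (SD, n = 3), 0.03 ± 0.02 in DLD1 TSA (n = 5), 0.24 ± 0.03 in DLD1+7 vehicle (n = 4) and 0.40 ± 0.07 in DLD1+7 TSA (n = 5). The difference between the lines was 0.26 under vehicle (95% interval 0.23 to 0.30, exact permutation p = 0.0286) and 0.37 under TSA (0.31 to 0.43, exact permutation p = 0.00794). On the 2 slides holding both lines under vehicle it was 0.29 and 0.26, and on 5 slides under TSA it lay between 0.30 and 0.48. The score rose with TSA by 0.05 in DLD1 (exact permutation p = 0.0179) and by 0.16 in DLD1+7 (exact permutation p = 0.0159), and in SW480 it went from 0.34 ± 0.01 to 0.41 ± 0.01 (exact permutation p = 0.0119). Tested across genes with the preset correlation, these rises were not past the threshold (p = 0.725, 0.299 and 0.691), and in DLD1 and SW480 other chromosomes rose more: chromosome 10 by 0.11 in DLD1 and chromosome 19 by 0.24 in SW480. In DLD1+7 the rise of chromosome 7 was the largest of any chromosome, the next being 0.10 on chromosome 10, while chromosome 22 fell by as much (-0.16). The rise was 0.10 larger in DLD1+7 than in DLD1 (SE 0.03, 95% interval 0.04 to 0.17 by the normal approximation, too narrow for so few arrays). Exact permutation of the line labels, which counts the difference between lines as spread, gave p = 0.549. Permutation of deviations from the group means, chosen after that result was seen, gave p = 0.00194, while the test across genes gave p = 0.117.

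Of the 93 chromosome 7 genes higher in DLD1+7 under vehicle, TSA lowered 16 in DLD1+7 (17.2%) and raised 30 further (32.3%). Among 752 genes of other chromosomes that were higher in DLD1+7 under vehicle, TSA lowered 125 (16.6%) and raised 318 (42.3%), and the shares lowered did not differ by Fisher's exact test (p = 0.883). Among all chromosome 7 genes tested, raised or not, 16.7% were lowered, against 19.2% on other chromosomes. Because a gene chosen as high under vehicle tends to fall on a second look at the same arrays, raised genes were also chosen with 2 of the DLD1+7 vehicle arrays and the response measured against the other 2. The shares lowered were then 10.1% on chromosome 7 and 10.4% elsewhere, averaged over the 6 such divisions. Among all genes tested, raised or not, the shares in these divisions were also lower, at 10.98% on chromosome 7 and 13.62% elsewhere. The drop from 17.2% therefore cannot be put down to the choice of raised genes alone. In data simulated without a TSA response in DLD1+7, 0% of raised chromosome 7 genes were called lowered, although 58.3% had a negative change. Among all chromosome 7 genes tested there, 0% were called lowered too, and 49.7% had a negative change. With no response in any gene almost nothing is called, so this 0% cannot tell how many lowered calls the choice of genes adds. Among the 93, the genes with the largest falls were ASB4 (-3.81), ZNF107 (-2.33, SE 0.30), the paraoxonase PON2 (-1.89, SE 0.19) and NOD1 (-0.99, SE 0.13), a receptor for bacterial peptidoglycan. Under TSA 77 of the 93 were still called higher in DLD1+7 than in DLD1. The difference between the lines was smaller under TSA than under vehicle for 70 of the 93, a direction that choosing them on the vehicle arrays also favours, and the interaction was called below 0 for 3 and above 0 for 4.

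**Figure D5:**
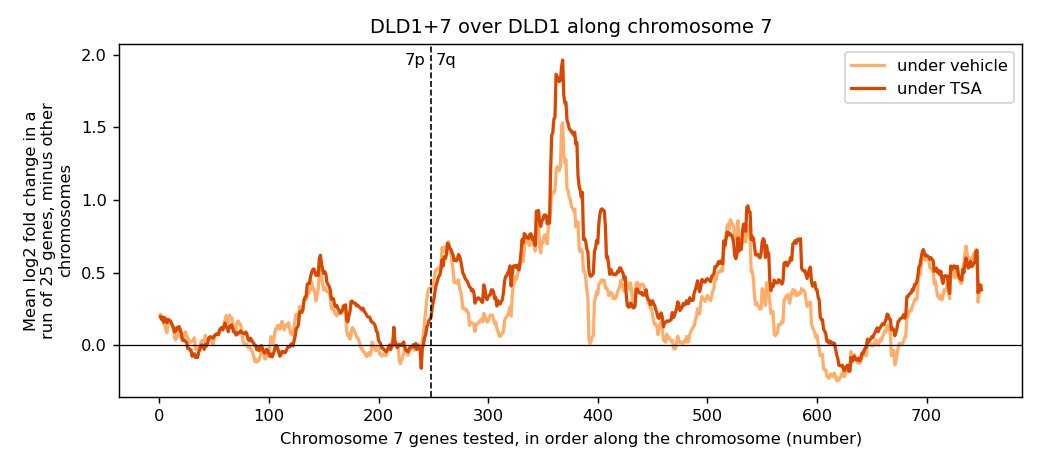
Running mean over 25 genes in chromosome order along chromosome 7 of the log2 fold change of DLD1+7 over DLD1, minus the mean of other chromosomes, under vehicle and under TSA. The mean shift was 0.09 on 7p and 0.35 on 7q under vehicle.

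The TSA response of DLD1+7 was compared with that of DLD1 gene by gene. Most of the genes that differed most were at background in some groups and well above it in others: TFPI2 (7.39, SE 0.97), FLNC (5.96, SE 0.92), TMEM130 (5.35, SE 0.73) and SGCE (4.56, SE 0.53), all on 7q, and the kallikrein KLK12 (5.30, SE 0.45) had the more positive change in DLD1+7. ASB4 (-3.97, SE 0.61), LINC00052 (-3.99, SE 0.37) and the synaptic adhesion gene SLITRK6 (-3.98, SE 0.49) had the more negative change. Each of these genes lacked a signal well above background in at least 1 group, so the sizes are less certain than the SE shows. In all limma called 99 of 15564 genes, 52 with a more positive and 47 with a more negative change in DLD1+7, and 1176 had an unadjusted p under 0.05. The count was 0 under normexp, 36 under normexp without far spots, 39 with the stricter filter, 59 without DLD1+7 vehicle replicate 3, 65 without the dim slide and 247 with the slide as a block. The 52.5% more positive became 35.8% with the authors' values, 42.5% with the slide as a block and 41.0% with the stricter filter. On chromosome 7, 11 genes were more positive (1.47% against 0.277% elsewhere; Fisher's exact p = 2.98e-05). DNA replication genes had a median of -0.53 with no member called (1 lower adjusted over the list alone; list adjusted p = 4.26e-06, adjusted p = 0.538 with an estimated correlation). Without DLD1 TSA replicate 1, where TYMS and MYB stood higher than on the other DLD1 TSA arrays, that median was -0.27 (adjusted p = 0.00356), so a part of it rests on 1 array. Of the 11 lists called here, only DNA replication and homologous recombination were called whichever array was left out. With an estimated correlation 3 lists had an unadjusted p under 0.05.

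The last comparison asked how SW480 and DLD1 differ in their response to TSA. The lists of neuronal and cholesterol synthesis genes had the more positive change in SW480, and those of glycolysis and of epithelial junction and keratin genes the more negative. None of these calls was kept with an estimated correlation (lowest adjusted p = 0.400 with an estimated correlation). IRGM (8.17, SE 0.99), UTS2B (8.14, SE 0.58) and STMN2 (7.13, SE 0.53) had the more positive change in SW480, and LGALS1 (-5.96, SE 0.46), VIM (-5.42, SE 0.38) and DUSP6 (-3.66, SE 0.30) the more negative. IRGM, UTS2B and STMN2 were not well above background on any vehicle array of either line, so their sizes and order are less certain than the SE shows. Of 16197 genes limma called 3838, 2087 more positive and 1751 more negative in SW480, 54.4% being more positive against 42.6% under median centring, where the median of all genes was -0.12. Neuronal genes were more positive in 15 of 31 cases and more negative in 1 (17 and 1 adjusted over the list alone; adjusted p = 2.37e-05, adjusted p = 0.400 with an estimated correlation). Cholesterol and fatty acid synthesis genes were more positive in 17 of 30 cases and more negative in 2 (20 and 2 adjusted over the list alone), with DHCR7 at 2.13 (SE 0.23; list adjusted p = 0.000131, adjusted p = 0.400 with an estimated correlation). Glycolysis and hypoxia genes were more negative in 10 of 28 cases and more positive in 2 (12 and 2 adjusted over the list alone), with NDRG1 at -2.73 (list adjusted p = 5.85e-05, adjusted p = 0.400 with an estimated correlation). Epithelial junction and keratin genes were more negative in 11 of 28 cases and more positive in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.00211, adjusted p = 0.509 with an estimated correlation). The unfolded protein and integrated stress response was more positive in 9 of 24 cases and more negative in 1 (9 and 2 adjusted over the list alone), with DDIT3 at 4.66 (SE 0.64; list adjusted p = 0.00988, adjusted p = 0.400 with an estimated correlation). In all 7 lists were called, and with an estimated correlation 4 had an unadjusted p under 0.05.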

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

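All tests of this part were planned. A difference in response was looked at more closely when its interaction term was called, and a sample when its gap to the nearest other sample of its group exceeded the Dixon limit.

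The response to TSA was called different between DLD1+7 and DLD1 for 99 genes, a count that ranged from 0 under normexp to 247 with the slide as a block. TFPI2 (7.39), FLNC (5.96), TMEM130 (5.35), KLK12 (5.30) and SGCE (4.56) had the more positive log2 change in DLD1+7, and LINC00052 (-3.99), SLITRK6 (-3.98), ASB4 (-3.97), SLC15A1 (-3.31) and NECTIN3 (-2.99) the more negative. TFPI2 was well above background on 2 of the 4 DLD1+7 vehicle arrays and all 5 DLD1+7 TSA arrays, and on no DLD1 array. SGCE was on all 9 DLD1+7 arrays and on no DLD1 array. SLITRK6 and NECTIN3 were on all 5 DLD1 TSA arrays, on no DLD1 vehicle array and on all DLD1+7 arrays. Under normexp the difference turned sign for SLITRK6 (0.24), NECTIN3 (0.39) and SLC15A1 (1.24), none of them called. Of 100 splits of the arrays, drawn at random with the real split among them, 2 called as many genes as the real 99, and the highest other split, which exchanged 4 TSA arrays of each line, called 1639. A count so far above the real one points to a structure of the samples: such splits put the difference between the lines into the interaction, so this count decides nothing about chance.

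The response differed between SW480 and DLD1 for 3838 genes. IRGM (8.17), UTS2B (8.14), NBEAP1 (7.65), STMN2 (7.13) and C1QTNF9 (6.98) had the more positive change in SW480, and CARD6 (-6.71), CACNG6 (-6.39), NFE2 (-6.28), LGALS1 (-5.96) and KRT23 (-5.96) the more negative. Of these only LGALS1 was well above background on every vehicle array of both lines, so the sizes and order of the others are uncertain. In 5 of 100 random splits, the real one included, as many genes were called, and the highest other called 7339. The highest exchanged 4 TSA arrays of each line, again a structure of the samples, so this count does not decide about chance either. Slides, medium and scan day differ between the lines and cannot be told apart from the line.

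On single arrays, CDKN1A had a log2 signal of -2.20 on DLD1 TSA replicate 3, where the other 4 DLD1 TSA arrays lay between -3.64 and -3.23. EGFR had -2.22 on DLD1+7 vehicle replicate 2, where the other 3 lay between -1.41 and -1.29. These were the only flags in 44 such tests of array measures and genes fixed by name, near the 1 in 20 that chance gives. Among the genes of largest change, 26 of 304 pairs of a gene and a group had such an array, and chance gives about 1 in 20. Their causes were not tested.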

How the results depend on the processing

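Normexp without far spots, the fit without the dim slide and the lists with 1 array left out were chosen only after the result was seen. Tested across genes, the shift of chromosome 7 under vehicle and under TSA kept its direction and its call in every setting except for 7p alone, and most named genes kept theirs. Of 633 values of named genes, 565 did so with the authors' values, 595 with median centring, 612 with quantile scaling, 616 with the mean of probes, 613 without the filter, 629 with the slide as a block, 396 under normexp and 572 under normexp without far spots, and nearly all others became weaker. Leaving out 1 array at a time, the counts ranged from 5349 to 6155 in DLD1 TSA, 5702 to 7291 in DLD1+7 TSA, 7339 to 8818 in SW480 TSA, 1045 to 1601 for the gain under vehicle, 1088 to 2208 for the gain under TSA and 3142 to 4068 for SW480 against DLD1. The shift ranged from 0.25 to 0.27 under vehicle and from 0.34 to 0.39 under TSA, with no call changed. Leaving out DLD1+7 TSA replicate 5, the array with conflicting labels, kept every count within 1.5 times that reported.

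The planned normexp correction changed most. It called 1902 genes in DLD1 TSA, 3919 in DLD1+7 TSA, 162 for the gain under vehicle, 141 under TSA, 1305 for SW480 against DLD1 and 0 for the interaction, where limma had 608 at an unadjusted p under 0.05. The correlation of DLD1 with DLD1+7 became 0.64 and with SW480 0.54. On 5 arrays between 5 and 9 spots had a local background far above their signal. On 4 of these (DLD1 vehicle replicate 1, DLD1 TSA replicate 3, DLD1+7 TSA replicates 2 and 3) low signals were compressed, the 1st percentile of the log2 signal lying between -1.08 and -0.64, and leaving the spots out put it between -4.18 and -2.71. On SW480 TSA replicate 3 it went from -3.91 to -4.70. With these spots left out the counts were 983 for the gain under vehicle and 36 for the interaction, and the other counts lay within 1.5 times those reported. Under normexp the sign turned for CXCL8 (-0.052) and PAGE2 (-0.00383) in DLD1 TSA, for CAMK2B (0.77), HOXA2 (0.24) and MET (-0.27) in DLD1+7 TSA, and for FEZF1 (-0.29), ZMAT3 (-0.78), TGFB2 (-0.29), RSAD2 (-0.45), CSF2 (-0.43), PTGS2 (-0.59), CDKN1A (-0.61) and EGFR (-0.29) in the gain under vehicle. It also turned for THY1 (0.18) in the gain under TSA, for SLITRK6 (0.24), SLC15A1 (1.24) and NECTIN3 (0.39) in the interaction, and for IFI44 (0.019), CXCL8 (0.55) and COL1A1 (0.19) in SW480 against DLD1. Without the far spots it turned for ZMAT3 (-0.23), PTGS2 (-0.017) and CDKN1A (-0.10) in the gain under vehicle and for CXCL8 (0.15) in SW480 against DLD1.

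The interaction count of 99 was the least stable. It was 39 with the stricter filter, which tests fewer genes, 65 without the dim slide, 247 with the slide as a block, and from 59 (without DLD1+7 vehicle replicate 3) to 116 (without DLD1+7 TSA replicate 5) with 1 array left out. With the slide as a block the gain called 2749 genes under vehicle and 2867 under TSA, of which 1482 and 1595 were among those reported. The gain called 826 genes under vehicle when only its 2 groups were fitted, which leaves fewer arrays for the variances, and 1061 under TSA with the authors' values. Asking also for a change of at least 2-fold left 3392 genes in DLD1 TSA, 3520 in DLD1+7 TSA, 4796 in SW480 TSA, 873 and 701 for the gain under vehicle and TSA, by construction. Without the filter on dim probes SW480 correlated with DLD1 at 0.51 and with DLD1+7 at 0.52. Taken alone, 7p gave shifts of 0.087 and 0.11 under vehicle and TSA, not past the threshold across genes but past it between arrays (exact permutation p = 0.0286 and 0.0159), and 7q a difference of shifts of 0.15, past it with the preset correlation (p = 0.0256) and not with an estimated correlation (0.119). With an estimated correlation 0 of the 80 list calls were kept, and with 1 array left out between 69 and 82 lists were called.

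The share of raised chromosome 7 genes lowered by TSA lay so close to that of other chromosomes that its direction turned easily. It lay below the other chromosomes at 14.3% with quantile scaling, 20.6% with median centring, 16.0% with the mean of probes, 11.5% with the authors' values and 19.3% under normexp without far spots, and stayed above them at 18.8% with the replicate number as a block. With 1 array left out it ranged from 12.5% (without DLD1+7 vehicle replicate 3) to 21.4% (without DLD1 vehicle replicate 1), and lay below the other chromosomes also without DLD1 TSA replicate 3, DLD1+7 vehicle replicates 1 and 2, and DLD1+7 TSA replicates 4 and 5. In none did Fisher's exact test find a difference.

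Other signs that turned belong to genes not called. MYC in SW480 TSA was 0.12 with quantile scaling, 0.10 with the authors' values, and 0.60, a call, with the replicate number as a block. It ranged from -0.25 (without SW480 TSA replicate 1) to 0.21 (without SW480 TSA replicate 4), turning also without SW480 vehicle replicates 1 and 3 and SW480 TSA replicates 5 and 6. MET in DLD1+7 TSA was -0.14 with median centring and ranged from -0.057 (without DLD1+7 vehicle replicate 2) to 0.17, turning also without DLD1+7 TSA replicate 4. MET in the gain under vehicle was -0.21 with the authors' values, -0.049 with the replicate number as a block and -0.044 without the dim slide. It ranged from -0.19 (without DLD1 vehicle replicate 1) to 0.17, turning also without DLD1+7 vehicle replicates 1, 3 and 4. EGFR was 0.038 with the mean of probes and 0.20 with the replicate number as a block in SW480 TSA. In the gain under vehicle EGFR was -0.0046 with the mean of probes and ranged from -0.054 (without DLD1 vehicle replicate 1) to 0.72. Other causes were not tested.

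In DLD1+7 TSA residuals correlated between arrays of the same replicate number (r 0.24 to 0.66) and of the same slide (0.33 to 0.66), and replicates 1 to 3 share both. In SW480 TSA r was 0.28 to 0.44 by number and 0.21 to 0.28 by slide, and in the gain under vehicle 0.50 to 0.57 by slide and -0.40 to 0.32 by number. With the replicate number as a block the TSA counts of DLD1+7 and SW480 were 6754 and 8387, and MYC in SW480 and 3 further lists there were called. On simulated data the interaction and the difference between SW480 and DLD1 each recovered 15% of changes of 1 on the log2 scale, against 54% for TSA in SW480.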

Other observations

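The permutation of deviations from group means, the parts of 7q, the lists with 1 array left out, the tests of neighbouring genes and of gaps between them were chosen only after the result was seen.

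Genes of 7p shifted less than genes of 7q in DLD1+7 over DLD1 under vehicle (0.09 against 0.35). Standard errors in this paragraph come from a bootstrap of genes. Lower signal of 7p genes is argued against by a 7q minus 7p difference of 0.27 (SE 0.05) among the brighter chromosome 7 genes. A few strongly raised 7q genes are argued against by a difference of medians of 0.22 (SE 0.04). A candidate explanation is that a contiguous part of 7p was not gained: the medians of 3 parts of 7p by gene order differed by 0.19 (SE 0.09), which leaves it open. The highest of these medians, 0.18 above other chromosomes, did not reach the 0.28 of 7q. The shift also varied within 7q, where part 5 of 6 by gene order (84 genes) had a median of -0.031 against other chromosomes, and the spread of these parts was not tested. A biological damping of 7p genes was not tested, and no DNA was measured here.

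By the fitted change, 20 of 750 chromosome 7 genes tested (2.67%) were raised at least 4-fold in DLD1+7 under vehicle, more than an extra copy of a gene would give. Elsewhere 139 genes (0.938%) were, a ratio of 2.84 (Fisher's exact p = 8.03e-05). Dim or noisy probes are not excluded by that ratio, since 7 of the 20, and 35 of the 139, were not well above background on any DLD1 vehicle array. Among the 7, the lower bounds of SGCE (2.615-fold) and FEZF1 (3.39-fold) were under 4-fold. Those of ASB4 (88.1-fold), CNPY1 (22.4-fold), MTERF1 (10.2-fold), GNG11 (7.36-fold) and SAMD9 (6.42-fold) were over it. ZNRF2P1, AUTS2, GSAP, STEAP1, NPTX2, SMO, TMEM139, KRABD3 and NOS3 were well above background on all 3 DLD1 vehicle arrays. CAMK2B, GNAI1, MDFIC and PTPRN2 were on 2 of them. Dim signal in DLD1 is argued against for the genes with bounds over 4-fold and those detected on all 3. Silencing in DLD1 that TSA lifts stays open: TSA raised 9 of the 20 in DLD1 (45.0%, 95% exact interval 23.1% to 68.5%) against 59.0% of the others, but the same DLD1 vehicle arrays chose the genes and served as the control, which raises both shares. STEAP1, MTERF1, SAMD9, GNG11, SGCE and ASB4 lie within 40 neighbouring genes of 7q (chance share 0.0250), although the gaps between the 20 genes were not closer than chance by a permutation test (p = 0.0788). SGCE, ASB4 and TFPI2 belong to an imprinted region, but TFPI2 was not among the 20. TSA raised 1 of the 6 neighbours in DLD1. Parental origin was not tested, so no account by imprinting can be given for these genes.

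The chromosome 7 shift was larger under TSA than under vehicle, by 0.11. Without the dim array DLD1 vehicle replicate 1 the difference was 0.10 (SE 0.04), and without its whole slide it was 0.112. Other single arrays moved it more, to 0.080 without DLD1+7 TSA replicate 4 and to 0.133 without DLD1+7 TSA replicate 5. These values argue against the dim array as the source of most of the difference. The SE is the spread of the difference, not of its change when an array is left out. Among 648 chromosome 7 genes well above background on every array it was 0.056 (SE 0.016 by bootstrap of genes). Tested across genes with the preset correlation it had p = 0.248, so genes near background in DLD1 may account for some of it. Whether more acetylation raises an added copy more than the resident ones was not tested.

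For the other counts, no other split that was run reached the real one, which argues against chance alone. With as few as 35 possible splits for a count, and replicates that may not be separate cultures, chance was not excluded. All possible splits were run except for DLD1+7 TSA and the gain under TSA, where 100 of 126 were drawn at random with the real one among them. In DLD1 TSA 1 of 56 splits, the real one, called as many as 5981 genes and the highest other called 3505. That other split set DLD1 vehicle replicate 1 and DLD1 TSA replicates 2 and 4 against the rest. These were the dimmest arrays of the 2 groups (75th percentiles of 434, 640 and 1032), so a split by brightness that mixed drug and vehicle also called many genes. In DLD1+7 TSA it was 1 of 100, and the highest other, close to the mirror of the real split, called 5480. In SW480 TSA it was 1 of 84, with 230 for the highest other. For the gain under vehicle it was 1 of 35, with 3, and for the gain under TSA 1 of 100, with 862. In DLD1+7 and SW480 arrays of the same replicate number, several of them on the same slide, had correlated residuals, and among splits that part as many pairs as the real one the highest called 5480 and 0 genes.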
